A study of Homo sapiens with 12 samples.

How the data were processed

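The 12 libraries were grouped into 4 sorted populations of 3 from their titles, and the sorting batch was taken from the labels. The submitters' processing notes name the aligner STAR 2.7.9 and the genome build GRCh38. The deposited table gave counts and TPM per gene, per the file headers. The name under which it was deposited speaks of adjusted counts, but what adjustment was made is not given in the sources used here.

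Each library code in the header was searched for in the title, description, source name and characteristics of every sample. Because no code was found, the 24 columns of per-sample values were not used, and the tests of expression planned before the data were examined were not run. These were quasi-likelihood tests of the 4 populations, of each step of the cycle, and of late S/G2 against G1. Gene list tests and alternatives were also planned. Gene identifiers, coordinates, gene types and the length of 1 transcript per gene were read with pandas 2.3.3 in Python 3.11.15. The gene identifiers and coordinates were compared with GENCODE release 29 on GRCh38. Coordinates are those of the deposited table. The rule for named genes required test results and named no gene. The reporter genes and lists were named because they had been fixed beforehand.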

Results

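Poly(A)-selected RNA was sequenced from BJ-Fucci cells, a line of human BJ-5ta fibroblasts immortalised with telomerase and carrying the Fucci4 fluorescent reporters of cell-cycle position. Cells were sorted by flow cytometry into 4 populations, named in the labels as early G1, G1, early S and late S/G2. Each population was represented by 3 libraries, 1 from each of 3 sorting batches, giving 12 libraries. The design implies comparisons of mature RNA levels among the 4 populations, from early G1 to G1, from G1 to early S, from early S to late S/G2, and from late S/G2 back to early G1.

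None of these comparisons is reported here, because the columns of the deposited table were not matched to the populations. The table held 12 columns of counts and 12 columns of TPM, a length-normalised abundance, each headed by a library code. Of these 24 columns, 0 carried a code that stood in the labels of any sample. The batch names in the labels were codes of a similar form but matched no column. Assigning columns by their order, or by the levels of cell-cycle genes within them, would have been a guess, and the second would have fixed the outcome of the comparisons in advance. Comparisons between populations were therefore not made. Columns with no matching sample were left out of every step, so depths and expression levels over the whole table were not analysed here either.

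The gene annotation of the table did not depend on that assignment. The table had 60649 rows with 60649 distinct gene identifiers and 59385 distinct gene names. Protein-coding genes made up 19955 rows (32.9%), long non-coding RNAs 16888 rows (27.85%) and processed pseudogenes 10163 rows (16.76%). The listed transcript had a median length of 3022 nucleotides for protein-coding genes and 862 nucleotides for long non-coding RNAs.

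The genes on the lists drawn up for the planned gene list tests were present among the gene names. All 54 genes of mitosis and cytokinesis on a list fixed before the data were examined were found, as were all 22 of replication licensing and initiation and all 36 of DNA synthesis and nucleotide supply. All 53 genes on a list of replication-dependent histones were also present, but whether poly(A) selection captured their RNA was not examined. Over all 24 lists, 642 of 642 entries were found. Presence in the table says nothing about expression.

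Fragments of CDT1, the replication licensing factor, GMNN, its inhibitor geminin, and SLBP, the histone stem-loop binding protein, are components of Fucci4 reporters. In GRCh38, CDT1 (ENSG00000167513.9) lay on the plus strand of chromosome 16 from 88803789 to 88809258, and GMNN (ENSG00000112312.10) on the plus strand of chromosome 6 from 24774931 to 24786099. SLBP (ENSG00000163950.13) lay on the minus strand of chromosome 4 from 1692731 to 1712344. Their RNA levels were not analysed here.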

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

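The alternatives described here were chosen after seeing the data, and those fixed before the data were examined were not run, since they need expression values by population. The number of value columns matched to a single sample was 0 when the exact code was searched. It was also 0 when letter case was ignored, when the digits were searched alone and when the code was allowed inside a longer word. Under these looser searches, a column whose code was found in several samples would not have been counted. The number of rows with a gene identifier in GENCODE release 29 was 37318 with version suffixes and 58337 without them. The count without suffixes left out the 44 rows whose gene identifiers were marked PAR_Y, while the count with suffixes ran over all rows. Coordinates were the same as in release 29 for all 37318 rows matched with suffixes and for 43607 rows matched without them. The table was therefore annotated with a different release. No paired analysis was possible because the value columns were not matched to samples, and so not to the populations and sorting batches that the labels give for each sample.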
